A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

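Messenger RNA of a Saccharomyces cerevisiae wsc1 mutant in the BY4741 background was compared with and without Zymolyase, an enzyme preparation that digests the β-glucan of the yeast cell wall. Per the labels, cultures grew in rich medium at 24 °C and were split, and 1 part received Zymolyase at 0.8 U/ml while the other went on untreated. Both parts were collected after 3 h. Total RNA of 2 cultures was reverse transcribed with Cy3 or Cy5, and each culture was hybridised on 2 arrays with the dyes exchanged, which gave 4 two-colour arrays. On arrays 1 and 3 the treated RNA carried Cy3, and on arrays 2 and 4 it carried Cy5. Which arrays shared a culture is not given in the sources used here. The untreated channel of array 2, and no other channel, is labelled as a hog1 mutant.

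The deposited values were log ratios, read here as log2, which the authors had made from both channels of each array. The base of the logarithm was not stated. If the base was another one, each log2 value would scale by a constant, each fold would change as a power, and the counts of genes at least 2-fold changed would differ. The normalization, the scanner software and the filter that left cells empty are not given in the sources used here. The deposited values had medians of -0.00017, -0.014, -0.013 and -0.015 on arrays 1 to 4 and were used without further centring. No intensities were used, so the signal behind each ratio is unknown and the number of arrays limits the precision.

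The file held 6207 rows of yeast open reading frames (ORFs) and 2 control rows, which were left out of all tests. Each ORF had 1 row. Of the ORF names, 5654 matched a table of gene names of assembly R64 and took its symbol, and 553 kept their ORF name. That table was used only for names and for finding repeated and neighbouring ORFs. Values were present for 1305, 2412, 4485 and 3933 ORFs on arrays 1 to 4. The 1264 ORFs with a value on all 4 arrays were tested.

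The direction of the ratios was not stated either. By a rule set beforehand, values would have been turned by dye had arrays of opposite dye orientation correlated below -0.1. Across the 1264 genes the mean of arrays 1 and 3 correlated with the mean of arrays 2 and 4 at Pearson's r = 0.311 and Spearman's rho = 0.107, so the values were taken as already turned and left as deposited. All values are given as treated over untreated. This direction is likely and not settled by the labels: its basis is that the sample titles name the exposure. The correlation bears only on whether the arrays share a direction, and not all pairs of opposite orientation correlated above 0 by rank. If it were the other way, every gene called higher would be lower.

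For each gene, the arrays of a culture were averaged, which cancels a dye effect if the arrays of a culture had opposite orientations, as the stated design says, and the mean of the 2 cultures was tested against 0 with lmFit and eBayes of limma. Because the pairing of arrays into cultures is unknown, the fit was made under both pairings that join opposite dye orientations (1 with 2 and 3 with 4, or 1 with 4 and 2 with 3). The larger p was kept for each gene, adjusted by Benjamini-Hochberg, and called at an adjusted p under 0.05. All tests are two-sided. The 2 hybridisations of a culture are technical repeats, so the 4 arrays are not 4 replicates. The SD given is over 4 arrays of 2 cultures and includes the difference between dye orientations. The p-value rests on the spread between the 2 culture means, where that difference cancels, and does not measure this SD. That spread leaves 1 degree of freedom per gene, and eBayes weighs it with a prior from all genes. The prior had 8.03 degrees of freedom for the pairing 1 with 2 and 3 with 4. The variance behind a p-value was therefore mostly that of genes in general, and genes with unequal arrays could be called. The smallest absolute mean log2 ratio of a called gene was 0.70. Genes changed at least 2-fold on the mean and in the same direction on all 4 arrays were counted without a test. The same count was made for the dye contrast (arrays 1 and 3 against 2 and 4) and for both contrasts between possible cultures.

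A total of 35 gene lists of yeast pathways, stress responses and cell types were compiled from general knowledge, and none was drawn from these arrays. The 29 lists with at least 3 measured genes were tested with cameraPR of limma on the moderated t of a 4-array fit with treatment and dye terms, with a preset correlation between genes of 0.01. This is a competitive test that sets a list against the other measured genes. Lists were measured in part, for example 5 of 26 iron regulon genes, 32 of 52 amino acid synthesis genes and 122 of 138 cytosolic ribosomal protein genes. Adjusted p-values are over the 29 lists. Members past the test per gene were counted with adjustment over all genes and adjusted over the list alone. Lists, tests, named genes and most alternatives were set before the data were examined. Exceptions are given where they are used. Named genes are the 10 highest and the 10 lowest by mean log2 ratio among the called genes with the same direction on all 4 arrays, up to 4 genes with the largest absolute mean per list described, and WSC1, HOG1, SLT2, RLM1, KDX1, LEU2, URA3 and MET17 whatever their values. Other genes named are said to have been chosen after their values were seen, or are members listed to make a count readable.

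The tests were first tried on simulated data: 20 sets of 1264 genes with 200 changed genes, with the dye effects and residual SDs of the real arrays and 50% of the residual variance between cultures. For the comparison of treated with untreated cells, 28.7% of the 2-fold changes and 82.4% of the 4-fold changes were called, all with the right sign, and on average 1.19% of calls were false. A list of 20 genes shifted by 0.5 reached p under 0.05 in 100% of the sets, and an unshifted list in 0%. The simulated genes had normal noise and varied independently of each other. In the real data, estimated correlations between genes in the 7 lists past the test were 0.13 to 0.34. The rates for lists and the share of false calls therefore need not hold for the real arrays.

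Alternatives were each pairing alone, the 4 arrays as independent replicates with and without a dye term, centring and scaling of arrays, genes measured on at least 3 arrays, robust eBayes, other thresholds, other set tests, and leaving out each array in turn. Added after seeing the data were the test limited to genes with the same direction on all 4 arrays, the test without repeated or unlisted ORFs, arrays 1 and 3 multiplied by -1, arrays of the same dye orientation taken as a culture, and leaving out arrays on the same genes. Except where the same genes are stated, a fit without 1 array took all genes measured on the other arrays. The array left without its partner stood for a culture and weighed as much as the remaining pair. Of both pairings the estimate with the larger p is given, so a gene value without an array is not a plain mean of the rest. List medians without an array are medians of plain means. Work was done in R 4.3.3 with limma 3.58.1, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. No wild-type arrays were analysed here, so nothing is said of how the response of the mutant differs from that of wild type.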

Results

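Expression was measured on 4 two-colour arrays in a yeast strain lacking WSC1, which encodes a plasma membrane sensor of cell wall stress, after 3 h with the wall-digesting enzyme preparation Zymolyase. Treated and untreated parts of 2 cultures were compared, with 2 arrays of opposite dye orientation per culture (n = 4 arrays of 2 cultures). The question was which genes respond to wall damage when this sensor is missing. Ratios were present for 21.0%, 38.9%, 72.3% and 63.4% of the 6207 ORFs on arrays 1 to 4. No ratio was given for WSC1 itself (YOR008C, listed as SLG1) on any array, so the deletion could not be checked from its own spot.

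Zymolyase changed the expression of 109 of the 1264 genes measured on all 4 arrays, of which 45 were higher and 64 lower in treated cells (limma, adjusted p under 0.05). The highest was NFG1 (YLR042C), a known wall stress gene, with a log2 ratio of 4.36 ± 1.5 (SD, n = 4 arrays of 2 cultures; adjusted p = 2.56e-06), or 20.5-fold. PRM5 (YIL117C), a membrane protein gene known as a target of the cell wall integrity (CWI) pathway, followed at 3.04 ± 0.95 (adjusted p = 0.000235), or 8.25-fold. Next came RTC3 (YHR087W) at 2.28 ± 0.24, the aldehyde dehydrogenase gene ALD3 (YMR169C) at 2.23 ± 0.38, and PUN1 (YLR414C), a plasma membrane protein gene tied to wall integrity, at 2.22 ± 0.40. NCW2 (YLR194C), which encodes a structural wall protein, stood at 2.12 ± 0.85. The low-affinity glucose transporter gene HXT1 (YHR094C) reached 1.90 ± 0.48, the wall mannoprotein gene CWP1 (YKL096W) 1.87 ± 0.20, the stress protein gene HSP12 (YFL014W) 1.84 ± 0.61, and the unlisted ORF YOL053C-A 1.83 ± 0.45. The adjusted p of these 8 genes lay between 0.000236 and 0.00137.

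**Figure D1:**
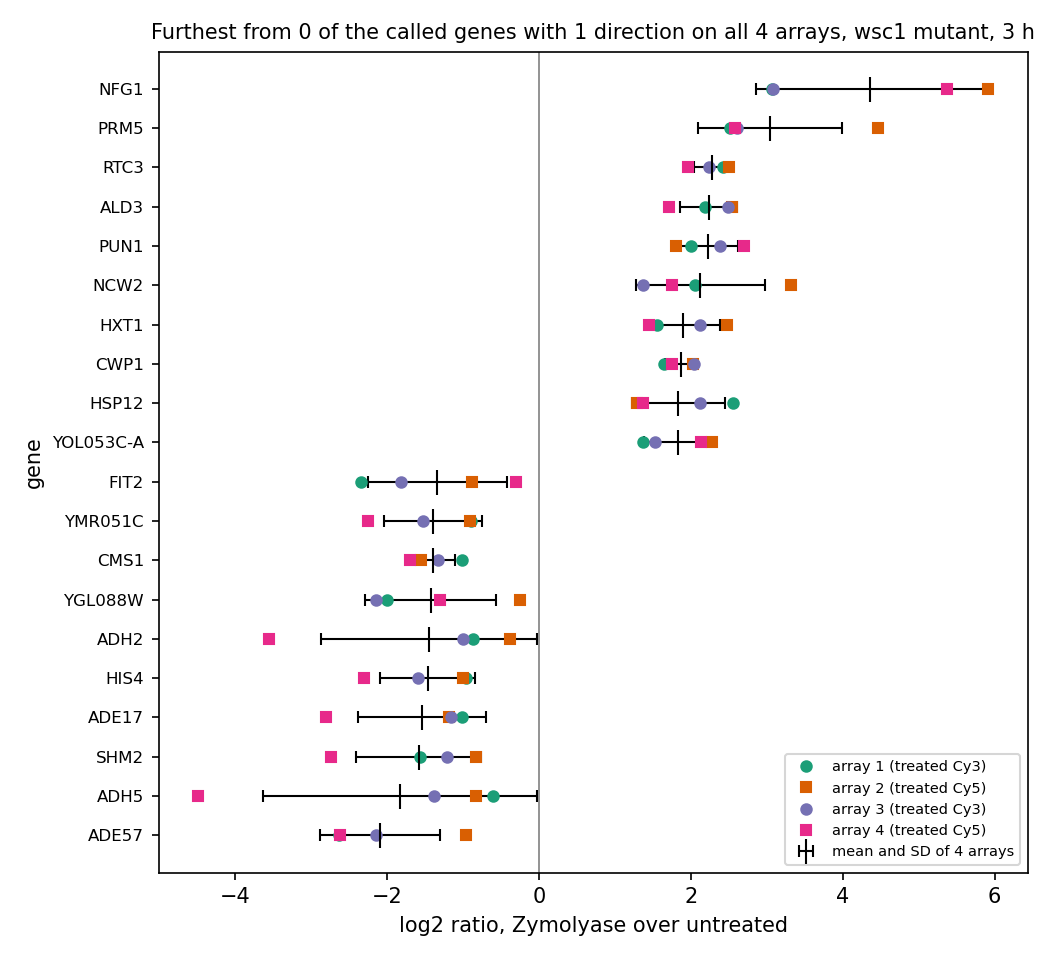
Log2 ratios of treated over untreated cells (x axis) for the 10 highest and 10 lowest of the called genes with the same direction on all 4 arrays (y axis); circles are arrays with the treated RNA in Cy3, squares arrays with it in Cy5, and bars the mean and SD of 4 arrays. NFG1 lies between 3.06 and 5.91 on the 4 arrays, while ADH5 and ADH2 have 1 array, array 4, far below the other arrays.

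Among the called genes with the same direction on all 4 arrays, the lowest was ADE57 (YGL234W), a gene of purine synthesis, with a log2 ratio of -2.09 ± 0.79 (adjusted p = 0.000348), or 4.26-fold lower. The purine and one-carbon genes SHM2 (YLR058C) and ADE17 (YMR120C) stood at -1.59 ± 0.82 and -1.54 ± 0.85, and the histidine synthesis gene HIS4 (YCL030C) at -1.47 ± 0.63. The alcohol dehydrogenase genes ADH5 (YBR145W) and ADH2 (YMR303C) had -1.83 ± 1.80 and -1.45 ± 1.43, with -4.49 and -3.55 on array 4 alone. Without array 4 they stood at -1.05 and -0.78 and were not called. Without array 3 they stood lower, at -2.60 and -2.09, and were not called either. YGL088W stood at -1.43 ± 0.87, CMS1 (YLR003C), a gene linked to ribosome assembly, at -1.40 ± 0.30, the retrotransposon-like ORF YMR051C at -1.40 ± 0.64, and FIT2 (YOR382W), a wall protein gene of the iron regulon, at -1.34 ± 0.92. FIT2 stood at -0.83 without array 1 and was not called then or without array 3. The adjusted p of these 10 genes lay between 0.000348 and 0.0263. By mean alone PUF4 at -2.10 ± 2.31 (adjusted p = 0.000348), HAC1 at -1.68 ± 1.42 and YLR162W at -1.57 ± 2.62 were also among the lowest called, but had values of 0.51, 0.12 and 2.24 on array 2. PUF4 and YLR162W are named after their values were seen. Without array 1 PUF4 stood at -0.70 and YLR162W at -0.13, and neither was called. In both estimates array 2 stood for a culture and weighed as much as arrays 3 and 4 together. YLR162W also lost its call without array 3 (-0.25) and without array 4, and stood at -2.89 without array 2, while HAC1 stood at -2.55 without array 2 and lost its call without array 3 (-0.82) and without array 4. FIT2 and its relative FIT3, the ADH family and the retrotransposon-like ORFs have similar copies, and their spots may read more than 1 transcript.

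Of the 109 calls, 39 of the higher and 53 of the lower genes had the same direction on all 4 arrays, and 17 genes did not. The number of calls depended strongly on single arrays: on the same genes, 36 were called without array 1, 117 without array 2, 18 without array 3 and 27 without array 4, and 35, 85, 18 and 27 of these were among the 109. The larger number of lower genes was not kept: there were 19 higher and 17 lower without array 1, 15 and 3 without array 3, and 19 and 8 without array 4, against 44 and 73 without array 2. With the 4 arrays taken as independent replicates and no dye term, 35 genes were called, and with arrays of the same dye orientation taken as a culture 29, all 29 among the 109. The 15 genes called in all 4 of these leave-out fits were NFG1, PRM5, RTC3, ALD3, PUN1, HXT1, CWP1, HSP12, YOL053C-A, YMR173W-A, PST1, SPI1 and YEL074W, all higher, and SHM2 and ADE57, both lower. YMR173W-A is known to overlap the CWI gene DDR48, so the spots of both may read the same transcript.

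By size alone, 50 genes were changed at least 2-fold on the mean and in the same direction on all 4 arrays, 18 higher and 32 lower. Without array 4 there were 29 higher and 14 lower, without array 1 36 and 44, without array 2 21 and 49, and without array 3 19 and 36. These counts asked for the same direction on the other arrays only. They also took more genes, 2311, 1282, 1266 and 1268 without arrays 1 to 4, so they do not show the effect of an array alone. The same count was 11 for the dye contrast and 0 for each of the contrasts between possible cultures. The same direction on all 4 arrays, at any size, was found for 279 genes (22.1%) with treatment and 245 genes (19.4%) with dye, against 59 (4.67%) and 94 (7.44%) for the contrasts between possible cultures. A share of 12.5% would be due to chance with 4 independent arrays, which these are not. Across genes, which are not independent replicates, arrays of the same dye orientation were the most alike, with Pearson's r = 0.734 for arrays 1 and 3 (rho = 0.627) and 0.359 for arrays 2 and 4 (rho = 0.269). The 4 pairs of opposite orientation gave r between 0.0573 and 0.287, with rho of -0.134 for arrays 1 and 2, -0.0207 for arrays 2 and 3, 0.194 for arrays 1 and 4 and 0.170 for arrays 3 and 4.

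Genes of the CWI signature, known targets of the kinase Slt2 and the transcription factor Rlm1 together with other wall stress genes, rose as a group. Of 35 genes on the list 17 were measured on all 4 arrays. Of these 17, limma called 12 higher and 0 lower, and 5 did not pass (14 higher when adjusted over the list alone). Without arrays 1, 2, 3 and 4 in turn, in fits on all genes measured on the other arrays, 8, 11, 6 and 7 were called higher and 0 lower. At an unadjusted p under 0.05 the list had 14 higher and 0 lower genes, and all 17 had a positive mean. The median log2 ratio was 0.99, with medians of 1.21, 1.70, 1.43 and 0.76 on arrays 1 to 4 (cameraPR, adjusted p = 8.31e-32). With an estimated correlation the call was lost (adjusted p = 0.862), as were all others, and fry on the means of 2 cultures, which tests a list against no change and not against other genes, gave an adjusted p of 0.785. Beside NFG1, PRM5, NCW2 and CWP1, the higher members included the wall protein genes PST1, SPI1 and PIR3 at 1.77 ± 0.37, 1.77 ± 0.42 and 1.60 ± 0.90, GFA1, which encodes the entry enzyme of chitin precursor synthesis, at 0.99 ± 0.72, and CRH1, a chitin transglycosylase gene, at 0.98 ± 0.32. Without array 2 GFA1 stood at 0.59 and was not called. The other 3 called were DDR48, GSR1 and YNL208W. The 5 that did not pass were GSC2 at 0.55 ± 0.93 (adjusted p = 0.212), CIS3 at 0.69 ± 0.38 (adjusted p = 0.0858), and SED1, PIR1 and HSP150. GSC2 passed without array 2 at 0.84 (adjusted p = 0.0334) and with scaling. It stood at 0.26, 0.015 and 0.97 without arrays 1, 3 and 4 and did not pass. CIS3 passed with centring and with scaling. Members beyond the first 4 are named after their values were seen, and SED1, PIR1 and HSP150 are set apart for their low values on array 4: they had values of 0.50 to 1.89 on arrays 1 to 3 and of -2.28, -2.19 and -2.60 on array 4.

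Targets of the high osmolarity glycerol (HOG) pathway also rose as a group, with 8 of 14 higher, 0 lower and 6 not past the test (10 higher when adjusted over the list alone), and a median of 0.82 (cameraPR, adjusted p = 6.88e-11; adjusted p = 0.862 with an estimated correlation and 0.785 with fry). The full list has 25 genes, of which these 14 were measured on all 4 arrays. The medians on arrays 1 to 4 were 1.02, 0.56, 1.08 and 0.15. Of its genes 3 were called without array 1, 8 without array 2, 2 without array 3 and 5 without array 4. ALD3 and HSP12 led the list. GPD1 and GPP2, genes of the glycerol synthesis pathway, stood at 1.56 ± 0.24 (adjusted p = 0.00114) and 0.97 ± 0.55 (adjusted p = 0.0195), and DAK1, a dihydroxyacetone kinase gene, at 0.98 ± 0.45 (adjusted p = 0.0201). The list of general stress genes of the transcription factors Msn2 and Msn4 had 6 of 20 genes higher, 0 lower and 14 not past the test (6 higher when adjusted over the list alone), a median of 0.40 and an adjusted p of 8.56e-05 (adjusted p = 0.862 with an estimated correlation and 0.785 with fry). The 20 were the measured part of 42 listed genes. The medians of this list were 0.61, 0.43 and 0.41 on arrays 1 to 3 and -0.19 on array 4. It lost its call without array 2 (adjusted p = 0.0589), and its median was 0.17 without array 1 and 0.25 without array 3. The 6 calls were 2, 5, 2 and 3 without arrays 1 to 4 in turn. Of its genes, 6 were shared with the HOG list, among them ALD3, HSP12, MSC1 at 0.89 ± 0.65 and RTN2 at 0.82 ± 1.04. MSC1 stood at 0.51 without array 1 and 0.61 without array 3, and RTN2 at 0.33 without array 1, 0.25 without array 3 and 1.40 without array 4, in each case without a call. Of the other 14, 1 was called and the median was 0.06. Of the 8 HOG targets on neither of the other lists, 3 were called and the median was 0.59.

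**Figure D2:**
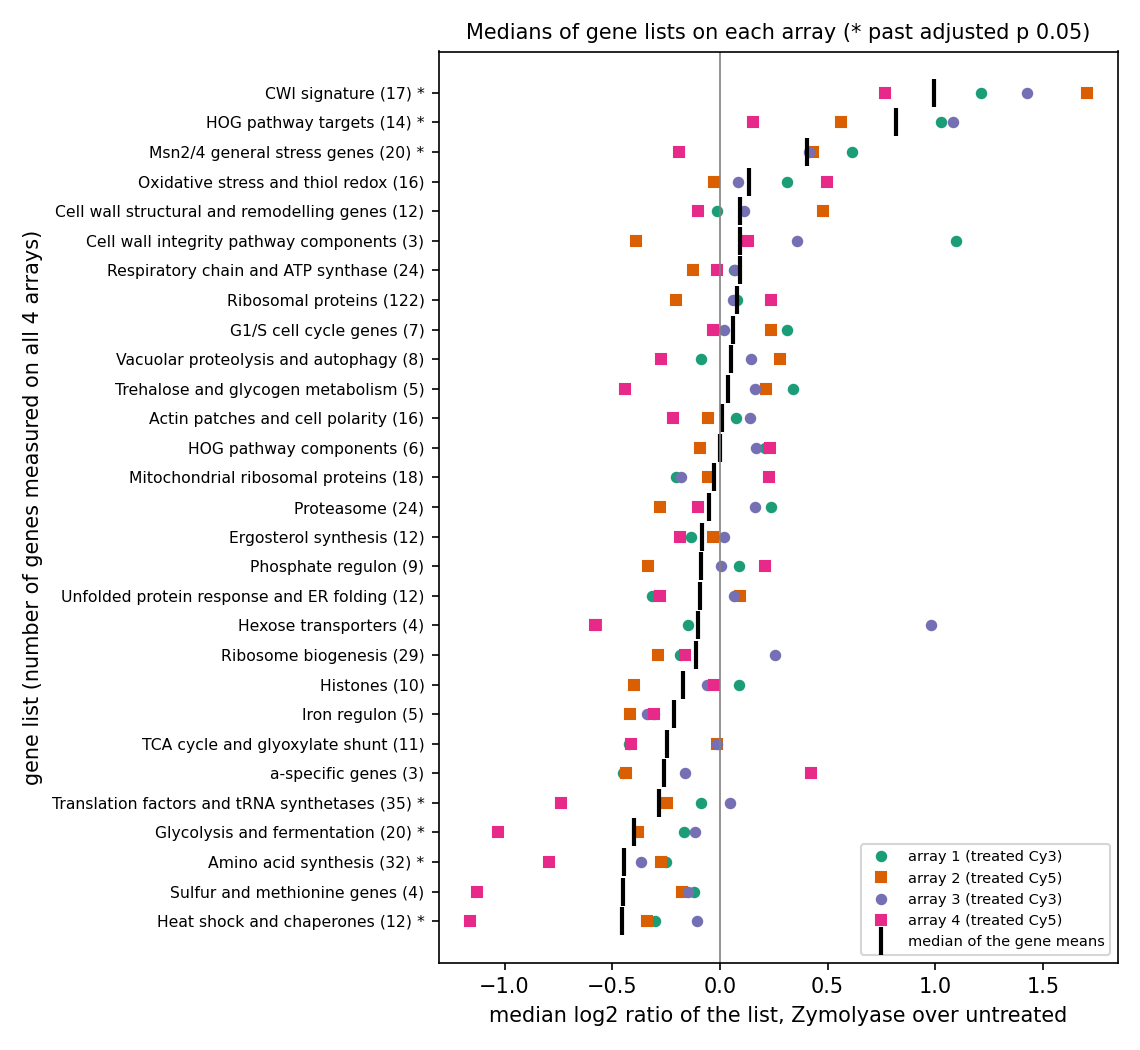
Median log2 ratio of treated over untreated cells (x axis) for each tested gene list (y axis, with the number of genes measured), on each array and for the gene means; circles are arrays with the treated RNA in Cy3, squares arrays with it in Cy5, and a star marks lists past the test. The CWI signature is positive on all 4 arrays, from 0.76 to 1.70, while the lower lists past the test have their lowest median on array 4.

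Amino acid synthesis genes, known targets of the transcription factor Gcn4, fell as a group. Of 32 measured, 8 were lower, 0 higher and 24 did not pass (10 lower when adjusted over the list alone), with a median of -0.44 (cameraPR, adjusted p = 1.74e-05; adjusted p = 0.862 with an estimated correlation and 0.785 with fry). After HIS4, the lowest were the asparagine synthetase gene ASN1 at -1.21 ± 0.35 (adjusted p = 0.00554), ILV2, a gene of branched-chain amino acid synthesis, at -1.08 ± 0.62, and the leucine synthesis gene LEU9 at -1.05 ± 0.79. The medians on arrays 1 to 4 were -0.25, -0.27, -0.37 and -0.79, and without array 4 the median of the list was -0.28 (adjusted p = 0.0019). All 8 calls were lost without array 3 and also without array 4, and 3 genes were called without array 1 and 7 without array 2.

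Lower values were also found for 3 further groups, each lowest on array 4. Of 20 genes of glycolysis and fermentation, 3 were lower and 0 higher (6 lower when adjusted over the list alone), with a median of -0.40 (cameraPR, adjusted p = 0.00683). The 3 called were ADH5, ADH2 and ADH3, the last at -0.90 ± 0.56, all alcohol dehydrogenase genes and none called without array 3 or array 4, while ADH1, which encodes the major fermentative one, did not pass at -0.67 ± 0.68 (adjusted p = 0.147). Of 12 heat shock and chaperone genes, 4 were lower and 0 higher (5 lower when adjusted over the list alone), with a median of -0.45 (adjusted p = 0.00705). These were SSA2 at -1.11 ± 0.91, HSP60 at -0.90 ± 0.54, HSP82 at -0.84 ± 0.79 and STI1 at -0.80 ± 0.53, while SSA1, a near copy of SSA2, had -1.11 ± 1.52 and did not pass (adjusted p = 0.0959). SSA1 had -3.37 on array 4 and stood at -0.30 without it, and it passed with centring, with scaling, without array 1 at -1.17 (adjusted p = 0.0147) and without array 2 at -1.06 (adjusted p = 0.00311). SSA2 stood at -0.61 without array 1, HSP82 at -0.48, -1.30 and -0.39 without arrays 2, 3 and 4, and STI1 at -0.50 without array 4, none of them called. Of 35 translation factor and tRNA synthetase genes, 2 were lower, FRS2 at -0.85 ± 0.68 and RPG1 at -0.80 ± 0.36, and 0 were higher (5 lower when adjusted over the list alone; FRS2 stood at -0.56 without array 1 and was not called), with a median of -0.28 (adjusted p = 0.0220). With an estimated correlation these lists had an adjusted p of 0.862, with fry 0.785, and without array 4 0.161, 0.104 and 0.201 in the order given, with medians of -0.22, -0.26 and -0.10. In all 3 lists 0 genes were called without array 3 and 0 without array 4, and without array 1 it was 2, 1 and 0 and without array 2 3, 2 and 3. The chaperone median was -0.68 without array 3, and with arrays centred and scaled the translation list had a median of -0.17 and an adjusted p of 0.0541.

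The other 22 tested lists did not pass. Among 122 cytosolic ribosomal protein genes limma called 0, with 1 higher and 2 lower at an unadjusted p under 0.05, and the median was 0.08 (adjusted p = 0.479). Over all 1264 genes 220 had an unadjusted p under 0.05. Wall structural and remodelling genes outside the CWI signature had 0 of 12 called by limma, with 2 higher and 1 lower at an unadjusted p under 0.05, and a median of 0.09 (adjusted p = 0.592). Among them was TIR2 at 0.68 ± 0.64, which passed with centring and with scaling. It stood at 0.89, 0.30, 0.77 and 0.48 without arrays 1 to 4 and passed in none of these fits. SUN4 at -0.69 ± 0.82 passed without array 2 at -0.98 (adjusted p = 0.00159). It stood at -0.20, -0.40 and -0.81 without arrays 1, 3 and 4 and did not pass. Components of the HOG pathway had 0 of 6 called by limma and 2 higher at an unadjusted p under 0.05, with a median of -0.00105 and a mean of 0.15 (adjusted p = 0.592, direction up). Of the CWI pathway components, 3 were measured on all 4 arrays and limma called 0, also at an unadjusted p under 0.05 (adjusted p = 0.814). RHO1 stood at 0.37 ± 0.61, and at 0.00077, 0.57, 0.18 and 0.54 without arrays 1 to 4. Of 5 iron regulon genes, FIT2 and FIT3 were lower, the latter at -1.05 ± 0.37 (list adjusted p = 0.234), and 0 were called without array 3 and 1 without array 1 or array 4. HXT1 was the 1 higher gene among 4 hexose transporters, while HXT3, HXT6 and HXT7 did not pass. The median of that list was -0.10 but its mean was 0.31 (list adjusted p = 0.407, direction up). In the unfolded protein response list of 12, HAC1, the transcription factor gene of that response, was lower at -1.68 ± 1.42 (adjusted p = 0.0184), with 0.12 on array 2 and -3.35 on array 3, -2.55 without array 2 and -0.82 without array 3 (list adjusted p = 0.592). GIC2 was higher among 7 genes of the G1/S list, at 0.81 ± 0.47, and 0.54 and not called without array 2 (list adjusted p = 0.455). A further 6 lists had fewer than 3 measured genes and were not tested.

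Some genes of the pathway itself were measured on a subset of the arrays and were not tested. SLT2 (YHR030C), the kinase gene of the CWI pathway, had log2 ratios of 2.20 on array 3 and 0.93 on array 4. Its paralog KDX1 (YKL161C) had 3.63 and 1.61 on the same arrays, and RLM1 (YPL089C) had 0.39 on array 3. HOG1 (YLR113W) had -0.17, 0.64, -0.14 and -0.38 on arrays 1 to 4 (mean -0.01 ± 0.45, adjusted p = 0.993). Of the marker genes deleted in BY4741, LEU2 had 0.10, -0.62 and 0.29 on arrays 2 to 4, URA3 had 2.91 on array 3 and no other value, and MET17 had none.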

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

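The tests of explanations in this part were chosen after the values had been seen. Each gene that the naming rule gives over all lists, and each list median, was examined for 1 array standing apart from the other 3. Of 126 genes named by rule 10 did, and of 29 lists 1 did, where chance gives about 1 in 20. A further 37 genes, named after their values were seen, were also examined, and 1 of these stood apart. Among all 1264 genes it was 83 (6.57%), with 25 low and 20 high on array 4, and 8, 17 and 13 on arrays 1, 2 and 3.

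PRM5 stood high on array 2 at 4.47, against 2.51 to 2.61 on the other arrays. HXT7 stood high on array 3 at 0.83, against -0.83 to -0.73, and NHP2 stood low on array 2 at -0.81, against 0.62 to 0.78. Low on array 4 were 7 genes named by rule: ADE17 at -2.81, SSA1 at -3.37, RPS0A at -1.38, ADH3 at -1.72, RPN10 at -0.89, RFA1 at -1.51 and OYE2 at -0.96. SED1, at -2.28 on array 4, was chosen for that low value and is not part of this count. The median of the sulfur and methionine list was -1.13 on array 4 and between -0.18 and -0.12 on the others. A control spot for Arabidopsis RNA, which took no part in the comparisons, had 2.01 on array 4 and -0.35 on array 3. URA3, deleted in this strain, had 2.91 on array 3.

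Many genes lay far below 0 on array 4: 27 were at or below -2 there, with a median of -2.30, and 11 of them were among the called genes. Their medians were -0.16, -0.38 and -0.35 on arrays 1 to 3. Since these genes were picked by their value on array 4, those medians do not decide between a difference of the culture, dye bias and a fault of the single hybridisation, which all remain open. Abundant transcripts reading low as a class on that array might produce the pattern, but the lists of abundant transcripts went apart. Against the mean of the other arrays the ribosomal protein genes lay a median of 0.20 higher on array 4 (quartiles -0.11 and 0.47), while glycolysis, chaperone and translation factor genes lay -0.81, -0.73 and -0.61 from it, so this stays open for the latter.

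Arrays of the same dye orientation resembled each other more than arrays of opposite orientation. Gene-specific dye bias left in the values may account for this. With the 4 arrays taken as replicates, limma called 12 genes for the dye term. A culture shared by arrays of the same orientation would enter the same term, so dye bias alone was not tested. The counts of 11 genes changed at least 2-fold by dye and 0 by each contrast between possible cultures follow from the same correlations and decide nothing. The buffer control spot had -0.29 and -0.13 with the treated RNA in Cy3 but 0.38 and 0.45 with it in Cy5, which is 1 spot and decides nothing for genes. Arrays of one orientation sharing a culture, against the stated design, cannot be told apart from dye bias by the correlations, since the lower of the same-orientation correlations, 0.359, exceeds the highest of the others, 0.287, under both. In the second case the difference removed as dye would be a difference between cultures, and keeping it as error left 29 of the 109 calls.

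The untreated RNA of array 2 is labelled as a hog1 mutant. Were that so, HOG1 would be expected far higher in treated over untreated on array 2, and it was 0.87 above the mean of the other 3 arrays, higher than the same deviation of 91.7% of genes. A mislabelled entry and a true hog1 sample cannot be told apart from this value, because the background that a deleted gene would give is unknown here and WSC1 had no ratio. The title of array 2 names the wsc1 mutant, and in the stated design both RNAs came from parts of the same culture. With a true hog1 sample, array 2 would compare strains as well as treatment.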

How the results depend on the processing

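Alternatives added after seeing the data were the direction filter, the removal of repeated ORFs, the turned arrays, the cultures of one dye orientation and the leave-out fits on the same genes. The cause of a shift was not tested except where stated. The 109 calls (45 higher, 64 lower) stayed within 1.5 times of these counts with either pairing alone (113 and 126), a dye term (115), centring (121), centring and scaling (136), genes on at least 3 arrays (104), robust eBayes (112), an adjusted p under 0.10 (142), the direction filter (92) and without repeated and unlisted ORFs (97). With 4 independent arrays and no dye term 35 were called (19 higher, 16 lower). With arrays of the same dye orientation as cultures it was 29 (17 higher, 12 lower). In both fits the difference between arrays 1 and 3 and arrays 2 and 4 counts as error, be it of dye or of culture. With arrays 1 and 3 turned it was 17 (5 higher, 12 lower). Leaving out 1 array gave 18 to 114 calls (15 to 43 higher, 3 to 71 lower), or 18 to 117 on the same genes (15 to 44 higher, 3 to 73 lower; 27 without array 4, 19 higher and 8 lower), where 0 of the 109 calls changed sign. Such a fit has 1 unbalanced dye and lets 1 array stand for a culture.

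The count of 50 genes (18 higher, 32 lower) at 2-fold became 117 (46 and 71) at 1.5-fold and 18 (15 and 3) at 3-fold, as the thresholds require. It was 51 with centring and 48 with centring and scaling, where the share of higher genes was 50% against 36%. With at least 3 arrays it was 74, with 31 higher among more genes. Without 1 array, also among more genes, it was 43 to 80, 19 to 36 higher and 14 to 49 lower.

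The 7 lists past the test were 7 with mean ratios, ranks or centring, 6 with scaling and 4 to 8 without 1 array. They were 0 with an estimated correlation and 0 with fry on culture means. In simulated sets of 20 independent genes shifted by 1, both of these reached p under 0.05 in 100% of sets, with lowest p of 0.0146 and 0.000609, before any adjustment over 29 lists. A lone list at the 0.0146 of the estimated correlation would not pass adjustment over 29 lists. That test could therefore hardly pass a list here, and its 0 decides nothing. The estimated correlations themselves, 0.13 to 0.34 in the 7 lists, lay above the preset 0.01. The adjusted p-values that cameraPR gave with the preset may therefore be too small. For fry the lowest simulated p, 0.000609, would pass that adjustment, so its 0 is not explained in this way. Before adjustment the larger p of fry over both pairings was 0.150 for the CWI signature and 0.125 for the HOG targets. The 7 list medians kept their sign in the 6 alternatives that change them (centring, scaling and 4 leave-outs). Of named genes called in the test, 0 changed sign with centring, scaling or leaving out 1 array. Of these, 34, 58, 18 and 24 passed without arrays 1, 2, 3 and 4, while 36, 12, 52 and 46 did not. The signal over background is unknown here, so what it limits was not examined.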

Other observations

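The lists in this part were written after the values had been seen, partly from genes already called, and no test of them as lists was made. Of 12 purine synthesis and one-carbon genes measured, 7 were lower and 0 higher, against 64 lower of all 1264 genes, the median log2 ratio was -0.93 and 9 were negative on all 4 arrays. Beside ADE57, SHM2 and ADE17, these were ADE1 at -1.07 ± 0.69, ADE2 at -1.01 ± 0.37, ADE13 at -1.01 ± 0.77 and ADE8 at -0.85 ± 0.40 (SD, n = 4 arrays of 2 cultures). The 7 calls became 6, 5, 2 and 3 without arrays 1 to 4 in turn. ADE1 stood at -0.71 without array 2 and -0.69 without array 4, and ADE13 at -0.64 and -0.66, none of these called. ADE3 and GCV2, measured on arrays 2 to 4, had -0.35, -1.23 and -1.35 and -0.45, -1.34 and -1.11.

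Retrotransposon-like ORFs and subtelomeric ORFs were also among the lower genes. Of 8 short Ty-like ORFs 7 were lower, with a median of -1.10, and of 10 long ones 1 was lower and 1 higher, with a median of 0.00. The higher one, YMR050C, had 2.23 and 2.26 on arrays 1 and 3 but -0.74 and -0.58 on arrays 2 and 4. Short and long ORFs were found by a shared end, so they overlap and their spots may read the same transcript. All 7 calls of short ones were lost without array 3 and also without array 4, and 3 genes were called without array 1 and 7 without array 2. Of the long ones 0 were called without array 1, 3 or 4, and 4 higher and 1 lower without array 2. Of 9 subtelomeric Y' ORFs 5 were lower, with a median of -0.77 and a range of -1.06 to 0.38. All 5 calls were lost without array 1, without array 3 and without array 4, and 2 were called without array 2. Copies of one family are nearly identical, so these spots are not independent measurements. Of the called genes, 6 were ORFs that the name table does not list: YEL074W, YLR391W, YMR173W-A, YMR304C-A, YOL053C-A and YOR248W.

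Many genes had values on arrays 3 and 4 but not on all 4. Among 2550 such genes, 23 were at least 2-fold higher on both arrays, 14 at least 2-fold lower on both and 6 at least 2-fold in opposite directions, and the correlation across genes was r = 0.236. Higher on both, chosen after their values were seen, were PPR1 at 2.58 and 2.72 (and 3.37 on array 2), CRG1 at 2.51 and 2.74, NQM1 at 2.53 and 2.07 (and 2.63 on array 2), SIP18 at 1.15 and 3.30 and AFB1 at 1.01 and 1.64 (and 4.38 on array 2). SIP18 and NQM1 belong to the HOG list, and AFB1 (YLR040C) is a near neighbour of NFG1. Lower on both were SEC14 at -2.15 and -3.12, YHB1, a nitric oxide oxidoreductase gene, at -1.44 and -2.04, and the malic enzyme gene MAE1 at -1.54 and -1.55. On array 2 SEC14, YHB1 and MAE1 had -0.65, -1.67 and -0.72. Array 2 did not always go the same way: MOR1 and YDR340W, higher on arrays 3 and 4, had 0.006 and -1.24 there. DEP1 and ZWF1, lower on arrays 3 and 4, had 0.56 and 0.49 on array 2. These values are without a test. URA3, deleted in this strain, had 2.91 on array 3, and the Arabidopsis control spot had 2.01 on array 4. A large ratio on 1 of these arrays need therefore not come from a transcript of the named gene.

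HIS3, which carries a partial deletion in BY4741, had -1.28, 0.23, -1.25 and -0.33 on arrays 1 to 4 (adjusted p = 0.0681). It passed without array 2 at -1.03 (adjusted p = 0.00419) and with scaling. It stood at -0.28, -0.29 and -0.89 without arrays 1, 3 and 4 and did not pass.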
